A study of Mus musculus with 6 samples.

How the data were processed

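Gene expression was measured in tibialis anterior muscle of mice in 6 samples, 1 Affymetrix array per sample: 3 from control C57Bl6J mice and 3 from mice carrying the MLC-SOCS-3 transgene on C57Bl6J. Per the labels, the mice were 11 weeks old, muscles were taken after 6 h of starvation and frozen in liquid nitrogen, and biotinylated cRNA was made from 300 ng of Trizol-extracted total RNA. The titles number replicates within each group, and nothing says that these come from separate animals, so the p-values measure the spread between these samples, which may be technical.

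The deposited table holds 1 value per probe set and array. The values are log2 intensities that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes; versions are not given in the sources used here. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a set into 1 value. Folds of weakly and very strongly expressed genes are compressed on this scale, and single probes can no longer be inspected. The values ran from 1.41 to 15.1, and the medians of the 6 arrays lay between 5.98 and 6.04, so the values were used as deposited, with no further background correction or normalization. The table has no detection calls and no counts, so precision is limited by the number of arrays, and a level is described only against 5.99, the median probe set. All 6 value columns were used.

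The table holds 35557 probe sets. The platform annotation, which can be old, lists 23410 of them. Of these, 21789 have 1 gene symbol and 1621 have several. The other 12147 are unnamed here. No probe set carried the control prefix that was to be left out, so all 35557 were tested. Symbols were updated through Entrez identifiers, which matched 21698 probe sets to the GRCm38.p6 gene table. That table was also used for the chromosome and the order of genes, without coordinates, because the files name no genome build. A gene with several probe sets (999 genes) was represented by the one with the highest mean over all 6 arrays, giving 19938 genes. Probe sets with several symbols were not used for named genes.

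The arrays labelled MLC-SOCS-3 were compared with the controls using limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided). Benjamini-Hochberg adjustment ran over all probe sets, with a threshold of 0.05. Differences are log2 values, MLC-SOCS-3 minus control, with moderated standard errors. Gene lists were compared with all other genes by camera with a preset inter-gene correlation of 0.01. The 27 lists with at least 5 measured genes were adjusted together. Camera with an estimated correlation and fry, which tests the list alone, were alternatives. The tests, the 29 gene lists, the rule for naming genes and the alternatives listed at the end were fixed before the data were examined, apart from those said to be added later. The rule was as follows. Socs3 came first. Then came up to 12 genes per direction with adjusted p under 0.05, with the largest difference and no overlap between groups. Where fewer passed, each direction was filled to 8 genes by the smallest unadjusted p, and predicted genes and olfactory receptors were counted but not described. From each list, up to 4 members with the smallest p were eligible. The unit and the expected scale held, and no test had to be changed.

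Runs of neighbouring genes were sought, after the first results had been seen, among 11020 protein-coding genes above the median level. Windows of 5 to 60 consecutive genes on 1 chromosome were scored by the absolute sum of their z-scores, less the mean over all genes scanned, over the square root of the number of genes. The highest score was set against 1000 random reorderings of the genes and against the other splits of the 6 arrays.

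The scripts were tested on simulated data for this comparison, drawn from the probe sets' means and moderated variances, with 200 changed genes in each of 5 simulations over 35557 probe sets. The main test called 90.4% of the 2-fold and 40.6% of the 1.5-fold changes, with at most 11 false calls. On the 23410 listed probe sets with a mean-variance trend and robust moderation, 98.6% of the 2-fold and 86.4% of the 1.5-fold changes were called, with at most 18 false calls. All changed genes lay above the median level. Moderated variances are also more alike between probe sets than the measured ones, so these shares are not the power in the real data. A list shifted by 0.2 was called in all 5 simulations, with at most 1 other list. Of a run of 13 genes, as many as in the run found in the data, all shifted by 0.45, at least 10 were found in each. The differences in the real run were uneven, from 0.0074 to 1.01, which this does not cover. The simulated probe sets varied independently of one another, so the list and run results do not cover genes that vary together.

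No array was a copy of another: at most 36 of the 35557 values were identical between any pair. Pearson correlations over all probe sets were 0.989 to 0.991 within groups and 0.988 to 0.991 between them. Alternatives were quantile normalization, centring on the median, trend and robust moderation, array weights, the replicate number as a block, a filter on dim probe sets, 1 probe set per gene, a threshold of 0.10, the mean of a gene's probe sets, and leaving out each array. Added after seeing the data were fits of only the listed probe sets (alone, with trend and robust moderation, and with the replicate block as well), the other Socs3 probe set, and the lists without the genes of the chromosome 10 run.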

Results

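Whole-tissue gene expression was profiled in tibialis anterior, a mixed limb muscle that the submitters chose because it is easy to remove and had shown strong expression of the transgene in their earlier work. SOCS-3 is a suppressor of cytokine signalling, an intracellular inhibitor of JAK-STAT and insulin receptor signalling. The comparison asks how transcript levels differ between 3 arrays of muscle labelled MLC-SOCS-3 and 3 arrays of control muscle from C57Bl6J mice. Each array gave a log2 RMA intensity for 35557 probe sets. The Y-linked genes Uty, Eif2s3y and Kdm5d lay between 7.37 and 9.37 on all 6 arrays and Xist between 3.73 and 4.26.

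Socs3, the gene of the transgene, was not higher on the arrays labelled MLC-SOCS-3. Its intensity was 7.15 ± 0.09 (SD, n = 3) there and 7.41 ± 0.03 (SD, n = 3) in control muscle. The difference of -0.26 (95% interval -0.43 to -0.08) did not pass limma's test over all probe sets (adjusted p = 0.80). The other Socs3 probe set gave -0.22 (adjusted p = 0.82). The sources used here do not say which part of Socs3 the transgene carries or whether the probes lie in it, so this value does not check the labels if they lie outside it. Every direction is therefore given for the arrays as labelled.

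No single gene passed the test between the labelled groups. The gene with the smallest p was Casp12, a caspase linked to stress of the endoplasmic reticulum. It measured 7.88 ± 0.05 (SD, n = 3) in controls and 6.74 ± 0.15 (SD, n = 3) on the arrays labelled MLC-SOCS-3, a 2.21-fold lower intensity. Its adjusted p in limma was 0.55, the smallest of all probe sets. Limma called 0 of 35557 probe sets at an adjusted p under 0.05, while 2105 had an unadjusted p under 0.05, against 1778 that chance alone would give. The excess lay in the unlisted probe sets, with 1006 against 607. The listed ones gave 1099 against 1170.5 and the genes 969 against 997, both below the chance number. Over all 35557 probe sets, a split of the arrays that mixes the groups gave 2306, above the 2105 of the labelled groups. Casp12 was the only gene called when 1 probe set per gene was tested. Among the 19938 genes, 271 of those at an unadjusted p under 0.05 were higher and 698 lower. With each array centred on its median, which moved the median of all genes from -0.016 to 0.0035, the split was 389 higher and 548 lower.

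The values of the other genes that the naming rule picked did not pass the test either. Among those with higher intensities, Apaf1, the scaffold of the apoptosome, differed by 1.01 ± 0.13 (SE), a 2.01-fold difference. Utp20, a factor of ribosomal RNA processing, differed by 0.52 ± 0.08, and Chpt1, an enzyme of phosphatidylcholine synthesis, by 0.50 ± 0.08. Scyl2 differed by 0.56 ± 0.10 and Washc3, a subunit of the WASH complex of endosomes, by 0.35 ± 0.06. Pdp2, a phosphatase that activates pyruvate dehydrogenase, differed by 0.54 ± 0.08. Adipoq, which encodes the fat-cell hormone adiponectin, differed by 0.64 ± 0.10, and the dynein gene Dnah7a by 0.67 ± 0.08. Their adjusted p-values lay between 0.61 and 0.73.

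Among those with lower intensities, Socs2, a member of the same inhibitor family as Socs3 and a target of STAT5, differed by -1.15 ± 0.17 (SE), a 2.22-fold difference. A second, dimmer Socs2 probe set gave -0.38 ± 0.11. Slc25a3, the phosphate carrier of mitochondria, differed by -0.56 ± 0.07. Trim72, a membrane repair protein of muscle, differed by -0.48 ± 0.07, and Exoc7, a subunit of the exocyst, by -0.36 ± 0.06. The serine protease genes Htra4 and Prss29 differed by -0.81 ± 0.10 and -0.56 ± 0.08, and the zinc finger gene Zfp991 by -0.61 ± 0.10. Adjusted p-values for these 7 genes lay between 0.61 and 0.73. Dnah7a, Adipoq, Prss29 and Zfp991 lay below the median probe set, where folds are compressed. When only the 23410 listed probe sets were tested, with a mean-variance trend and robust moderation, an alternative chosen after seeing the data, limma called 11 probe sets. Casp12, Slc25a3, Trim72, Htra4, Socs2 and Msrb1 were lower, and Apaf1, Chpt1, Mybpc1, Utp20 and Scyl2 were higher.

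**Figure D1:**
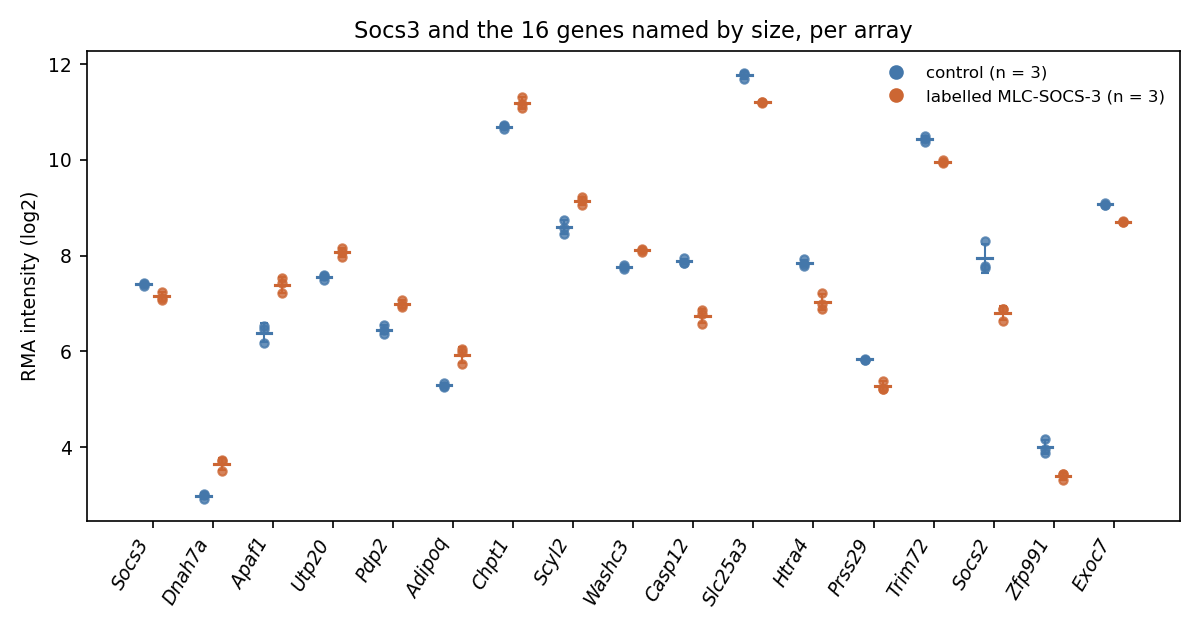
Log2 RMA intensity of Socs3 and of the 16 genes picked by the naming rule, for each array (points), with the mean (horizontal bar) and SD (vertical bar) of 3 control arrays and 3 arrays labelled MLC-SOCS-3. Socs3 averaged 7.41 in controls and 7.15 on the arrays labelled MLC-SOCS-3, and Casp12 7.88 and 6.74. The groups did not overlap for any plotted gene, which also held for 11.8% of all probe sets, against 10% by chance. Picking the 16 genes by smallest p on these arrays favours such genes, so this is no separate support for them.

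Of the 16 genes, 7 lie on chromosome 10, and 5 of these, all higher (Washc3, Chpt1, Utp20, Scyl2 and Apaf1), are close neighbours in gene order. Slc25a3, which was lower, lies close to Apaf1 as well. A scan over 11020 expressed genes, made after this had been seen, found its highest score, 9.27, in the 13 consecutive genes from Nup37 to Apaf1. None of 1000 random reorderings scored above 5.47 (permutation test, p = 0.001, the smallest they can give, 1 scan). The reorderings keep the labelled groups fixed and treat neighbouring genes as independent, so this p does not measure the spread between samples. The window is chosen for its summed differences, and its 13 genes had positive ones, with a median of 0.48. Nup37, Gnptab, Dram1, Arl1, Ikbip, Tmpo and Nedd1 were named after their values were seen. The run included Mybpc1, which encodes slow myosin-binding protein C, at 0.26 ± 0.06 (SE), and Gnptab, an enzyme of lysosomal protein sorting, at 0.40 ± 0.08. Dram1 (0.0074 ± 0.10) and Arl1 (0.059 ± 0.07) were close to 0. The 20 flanking genes had a median of -0.047, but the genes next to Apaf1, Ikbip and Slc25a3, were at -0.41 ± 0.11 and -0.56 ± 0.07. Nedd1, further on the same side, was at -0.29 ± 0.07, and Tmpo between them at -0.12 ± 0.09.

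**Figure D2:**
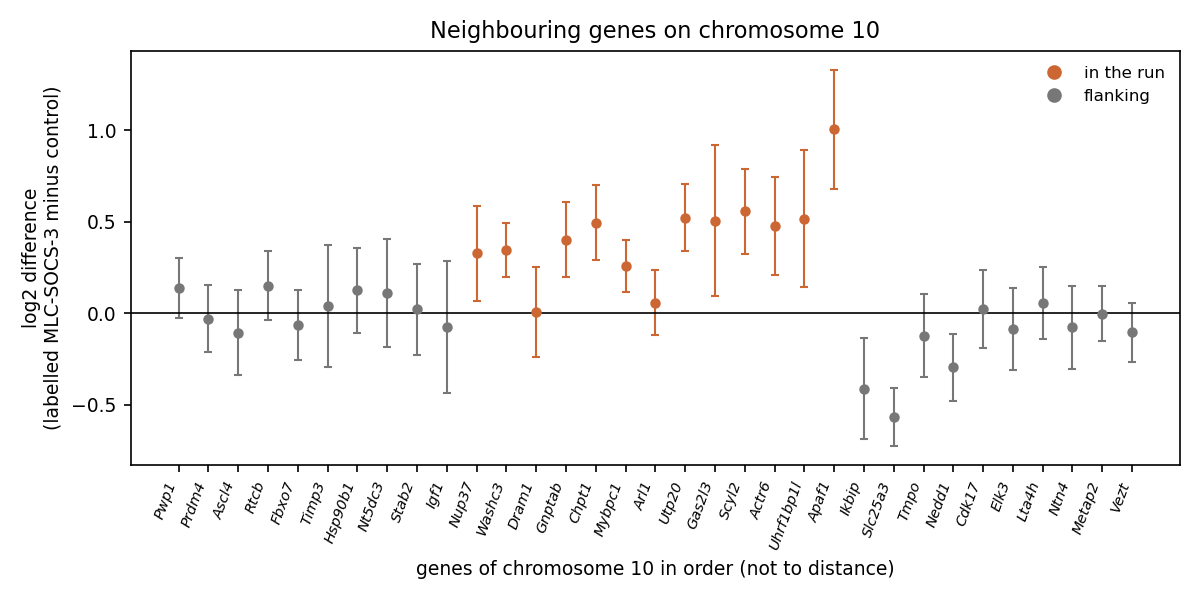
Log2 difference, arrays labelled MLC-SOCS-3 minus control (3 arrays each), with 95% intervals from limma, for the 13 genes of the run and 10 expressed genes on each side, in their order on chromosome 10 and not to distance. The genes from Nup37 to Apaf1 lie at or above 0 with a median of 0.48, against -0.047 for the flanking genes.

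The list of JAK-STAT signalling genes was not called by camera (adjusted p = 0.34). Its median difference was 0.0032 and its mean -0.13, with 15 genes positive and 14 negative. Socs2 at -1.15 and Cish at -1.37 weigh on that mean. The mean was lower on all 3 arrays labelled MLC-SOCS-3 than on any control array. Chance alone separates 3 arrays from 3 in 10% of cases, and the fast fibre and Schwann cell lists, also not called, were separated too. Of the 29 measured genes, none passed over all genes. Adjusted over the list alone, 2 fell and 0 rose. These were Socs2 and Cish, both feedback inhibitors that STAT5 induces. Socs2 was represented by its brighter probe set. Its other probe set, which did not enter the list, gave -0.38 ± 0.11 (limma, unadjusted p = 0.016). Cish fell by 1.37 ± 0.27 (SE), a 2.58-fold difference (adjusted p = 0.73 over all genes and 0.031 over the list alone). Stat3 was at -0.30 ± 0.07 and Bcl3 at -0.24 ± 0.07.

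The 8 lists that camera called with the preset correlation were 5 higher and 3 lower, and none of the 27 lists held with an estimated correlation or with fry. Genes of fatty acid uptake and oxidation were higher as a list (adjusted p = 0.00257), by a median of 0.056, with 21 of 27 genes positive. Its adjusted p was 0.63 with an estimated correlation. No gene of the list rose or fell after adjustment over all genes or over the list alone. The mitochondrial carnitine carrier Slc25a20 was at 0.18 ± 0.06 (SE), the uncoupling protein Ucp3 at 0.21 ± 0.07 and Pdk4, which inhibits pyruvate dehydrogenase, at 0.16 ± 0.08. Lipoprotein lipase, Lpl, was at -0.14 ± 0.07. The mean of the list was higher on all 3 arrays labelled MLC-SOCS-3 than on any control array, a separation that chance gives in 10% of cases. The list of oxidative phosphorylation and the TCA cycle was also higher (adjusted p = 0.00622, and adjusted p = 0.64 with an estimated correlation), by a median of 0.024, with 42 of 57 genes positive. Its genes Ndufb3 and Ndufs4, subunits of complex I, were at 0.17 ± 0.08 and 0.11 ± 0.06, and none passed over all genes or over the list alone. The list mean was -0.0010 on MLC-SOCS-3 replicate 1, below control replicates 1 (0.012) and 3 (0.0049). Without control replicate 2 the list was not called (adjusted p = 0.26).

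Connective tissue genes were higher as a list (adjusted p = 3.73e-05, and adjusted p = 0.63 with an estimated correlation), with 21 of 22 genes positive and a median of 0.12. None of these genes passed over all genes or over the list alone. The collagen Col3a1 was at 0.28 ± 0.14 (SE), the matrix protease Mmp2 at 0.22 ± 0.10, and the fibroblast receptor Pdgfra at 0.16 ± 0.07. The list mean was -0.16 on MLC-SOCS-3 replicate 1, below the controls at -0.10 to -0.06, and 0.22 and 0.18 on replicates 2 and 3. Macrophage markers were higher as a list (adjusted p = 0.00432, and adjusted p = 0.63 with an estimated correlation), with 16 of 19 genes positive. Its mean was -0.13 on MLC-SOCS-3 replicate 1, below control replicates 2 (0.12) and 3 (-0.066). Adjusted over the list alone, 1 rose, the integrin gene Itgam at 0.57 ± 0.11, which lay below the median probe set, and over all genes none. Cd68 was at 0.51 ± 0.29. It read 6.34 on MLC-SOCS-3 replicate 1, below every control (6.47 to 6.54), and 7.21 and 7.49 on replicates 2 and 3. The macrophage call ended without control replicate 1 (adjusted p = 0.50), MLC-SOCS-3 replicate 2 (0.0673) or MLC-SOCS-3 replicate 3 (0.0997).

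Adipocyte markers were higher as a list (adjusted p = 0.0211, and adjusted p = 0.63 with an estimated correlation), with 8 of 12 genes positive. Adjusted over the list alone, 1 rose, Adipoq, and over all genes none. Plin1, which coats lipid droplets, was at 0.21 ± 0.10 (SE) and Lep, the leptin gene, at 0.26 ± 0.13. That call ended without control replicate 2 (adjusted p = 0.21), MLC-SOCS-3 replicate 1 (0.051) or MLC-SOCS-3 replicate 3 (0.0752), and on probe sets above the median level (0.38), where Adipoq, Plin1 and Lep are absent.

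The 3 lists called lower were tendon, immediate-early and lymphocyte genes. Tendon genes were lower by a median of 0.19, with 8 of 10 genes negative (adjusted p = 0.00708, and adjusted p = 0.63 with an estimated correlation). Adjusted over the list alone, 2 fell, the tendon transcription factor Mkx at -0.35 ± 0.07 (SE) and the matrix gene Cilp2 at -0.36 ± 0.08, and over all genes none. Mkx lay below the median probe set. The list mean was -0.133 on control replicate 1, below all 3 arrays labelled MLC-SOCS-3 (-0.128 to -0.034), and 0.22 and 0.17 on control replicates 2 and 3. The tendon call ended without control replicate 2 (adjusted p = 0.26), control replicate 3 (0.11) or MLC-SOCS-3 replicate 3 (0.058). Genes of the immediate-early response, which rise within minutes of stimulation or handling, were lower (adjusted p = 0.0206, and adjusted p = 0.63 with an estimated correlation). Of its 16 genes, 11 were negative and none passed over all genes or the list alone. Dusp1 was at -0.81 ± 0.21 and Nr4a1 at -0.44 ± 0.14. Control replicate 2 had a list mean of 0.45 and control replicate 3 one of -0.18, while MLC-SOCS-3 replicate 3, at 0.077, lay above control replicates 1 and 3. The call ended without control replicate 2 (adjusted p = 0.35) or MLC-SOCS-3 replicate 1 (0.38). Lymphocyte markers were lower (adjusted p = 0.0467, and adjusted p = 0.63 with an estimated correlation), with 8 of 12 genes negative and none passing over all genes or the list alone. The call ended without any 1 of the 6 arrays (adjusted p between 0.0528 and 0.175), with an estimated correlation, with fry and in 4 further settings. Cd3g, a subunit of the T cell receptor complex, was at -0.30 ± 0.09 and the granzyme gene Gzmb at -0.21 ± 0.07, both below the median probe set.

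**Figure D3:**
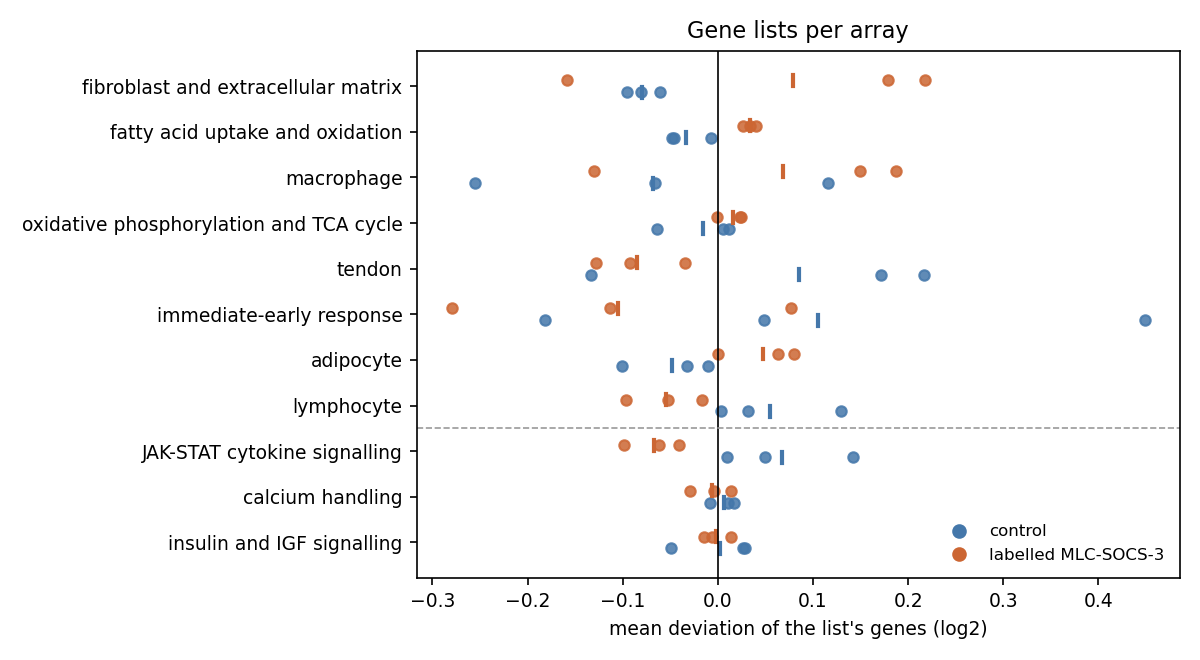
For each array, the mean over a list's genes of the deviation from each gene's own mean over the 6 arrays (log2), for 3 control arrays and 3 arrays labelled MLC-SOCS-3, with short vertical bars at the group means. Above the dashed line are the 8 lists that camera called with the preset correlation, none of them with an estimated correlation, and below it are JAK-STAT signalling, calcium handling and insulin signalling, which were not called. MLC-SOCS-3 replicate 1 has the lowest value of the connective tissue list, -0.16.

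Genes of muscle contraction and calcium handling gave no called list. For the 28 calcium handling genes the median difference was -0.014 (adjusted p = 0.90). Mrln, a peptide inhibitor of the calcium pump, was at -0.25 ± 0.08 (SE), and Pln, another inhibitor of the pump, at 0.21 ± 0.11. The calcium channel subunit Cacna2d1 was at 0.11 ± 0.07 and Jph1, which joins the calcium store to the surface membrane, at -0.10 ± 0.06. The lists of calcineurin-NFAT and MEF2 (adjusted p = 0.55), slow fibre (0.41), fast fibre (0.56) and sarcomere genes (0.17) were not called, with medians between -0.030 and 0.018. The sarcomere list was called higher without control replicate 1 (adjusted p = 0.0369). Myoz2, a calcineurin-binding protein of slow fibres, was at -0.52 ± 0.21, and the slow troponin Tnnt1 at -0.21 ± 0.09. Control replicate 1 stood apart for Myoz2, at 10.23 against 9.48 and 9.52 on the other controls. The fast myosin genes Myh2 and Myh1 were at -0.30 ± 0.15 and 0.06 ± 0.06. Myh2 read 12.52 on control replicate 1, against 11.97 and 12.01 on the other controls. Myogenesis and regeneration (adjusted p = 0.34, Myod1 at -0.48 ± 0.18), neuromuscular junction and denervation (0.34, Etv5 at -0.20 ± 0.07) and atrophy and autophagy genes (0.17) were not called. Without control replicate 2 the atrophy and autophagy list was called higher (adjusted p = 0.000376). Its member Gadd45a, a gene induced by stress and denervation, was at 0.27 ± 0.14.

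Insulin and IGF signalling genes were not called (adjusted p = 0.69). Their median was -0.016 and their mean -0.0041, while camera's direction was up. Tbc1d1, a regulator of glucose transporter traffic, was at 0.35 ± 0.10 (SE). Glycolysis and glycogen genes were not called (adjusted p = 0.68, median -0.015, camera's direction up), with Hk2 at 0.22 ± 0.19. Hk2 read 12.81 on MLC-SOCS-3 replicate 3, against 12.42 and 12.19 on replicates 1 and 2 and a control mean of 12.26. Lipid and sterol synthesis genes were not called (adjusted p = 0.34). Its member Scd1, a fatty acid desaturase, was at 0.54 ± 0.12, and Srebf1, a regulator of lipid synthesis, at -0.38 ± 0.10. The lists of the proteasome (adjusted p = 0.16), the unfolded protein and heat shock response (0.17), interferon and antigen presentation (0.17) and the circadian clock (0.34) were not called. The proteasome list was called higher without MLC-SOCS-3 replicate 2 (adjusted p = 0.0269), and the unfolded protein and heat shock list without control replicate 1 (0.0400) or MLC-SOCS-3 replicate 1 (0.00146). Interferon and antigen presentation genes were called lower without control replicate 1 (0.0252) and on probe sets above the median level (0.000609). In that list Oas1a, an antiviral enzyme gene, was at 0.64 ± 0.20 and the immunoproteasome gene Psmb10 at -0.17 ± 0.06. The markers of endothelial cells (0.41), Schwann cells and nerve (0.17) and smooth muscle and pericytes (0.72, with the median at -0.030 and camera's direction up) were not called either. All 8 measured Schwann cell and nerve genes were negative, with a median of -0.10, and the list was called lower without control replicate 1 (0.0369). Only 2 of the blood genes were measured, too few for the test, with Alas2 at 0.15 ± 0.07 and Slc4a1 at -0.19 ± 0.12. Over the 19 lists that were not called, only Socs2 and Cish passed when adjusted over the list alone, and no gene passed over all genes.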

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

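The settings with only listed probe sets, the other Socs3 probe set and the lists without the chromosome 10 run were added after seeing the data. The count of 0 called probe sets was the same with arrays quantile-normalized again, each array centred on its median, trend and robust moderation, array weights, the filter on dim probe sets, a threshold of 0.10, and only the listed probe sets. It was 1 with only the representative probe set of each gene (Casp12), and 0 to 1 when single arrays were left out (an unnamed probe set at -2.74, without control replicate 2). With only listed probe sets, trend and robust, it was 11. The same with the replicate number as a block gave 3 (Apaf1, Slc25a3 and Casp12). The cause of these changes was not tested. The replicate block alone gave 0 called probe sets, Socs3 at -0.26 and 7 called lists. Same-numbered arrays did not deviate together (correlations of -0.043 to -0.018), and 0 of the 6 arrays correlated best with their own number, so the numbers are not taken to pair the samples, and a call lost under the block is no sign of a weaker effect. Socs3 stayed negative and uncalled in all settings, from -0.31 to -0.22. The number of called lists was 8 in the main setting, 0 with an estimated correlation, 0 with fry and 4 to 10 when single arrays were left out (4 without control replicate 2 and 4 without MLC-SOCS-3 replicate 3). It was 7 or 8 in the other settings. Over 16 alternatives, the connective tissue and fatty acid lists were called in 14, oxidative phosphorylation in 13, immediate-early in 12, macrophage and tendon in 11 and adipocyte in 10, and the lymphocyte list in 3 of 15, each with a highest adjusted p of 0.63 or 0.64. The lowest was 1.56e-13 for connective tissue (without MLC-SOCS-3 replicate 1), 3.10e-08 for tendon (without control replicate 1), 6.32e-07 for macrophage (without control replicate 2), and between 9.32e-05 and 0.0321 for the others. Values per gene were not tallied for the fits of 1 probe set per gene, of listed probe sets alone and of listed probe sets with the block, whose calls are given before. Of the 1528 values of 119 genes under the other alternatives, 1517 kept their direction and their side of the threshold and 10 newly passed it, with listed probe sets, trend and robust. The remaining one was Pdgfrb, uncalled at 0.065, which turned to -0.017 without control replicate 2 (range -0.017 to 0.17 when single arrays were left out). The lymphocyte list had fewer than 5 genes above the median level and gave no value there. RMA values without detection calls leave the differences of dim probe sets, such as Dnah7a and Zfp991, without a check against background.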

Other observations

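The tests in this part were chosen after the results had been seen, other than the counts over splits of the arrays for all probe sets and for gene lists. Outside the fixed lists, Tmem100, a transmembrane protein of endothelium, was at -1.15 ± 0.22 (SE), and Iigp1, an interferon-induced GTPase, at -0.72 ± 0.14, in limma's fit (adjusted p = 0.73 for each). Both were chosen after their values were seen. The unlisted probe sets, 12147 of 35557, made up 247 of the 432 with an unadjusted p under 0.01. They had a median SD within groups of 0.21, against 0.11 for listed ones.

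The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 probe sets and the highest other split 1, so 10 of the 10 splits gave as many. With only listed probe sets, trend and robust, the real split called 11 and the highest other 2. For gene lists, the real split called 8 and the highest other 7, and 1 of the 10 splits gave as many.

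For the run of 13 neighbours on chromosome 10, the scan scored 9.27 for the labelled groups and at most 5.16 for another split. The reorderings, which reached 5.47, argue against a chance placement of changed genes. On a scale without compression, an extra copy of the whole run would add 0.58 to each gene. The differences were uneven, from 0.0074 for Dram1 to 1.01 for Apaf1. The unadjusted limma intervals of 5 of the 13 genes exclude 0.58 (Washc3, Dram1, Mybpc1 and Arl1 below it, Apaf1 above it). Among the 10 genes not above the level of the 90th percentile, only 3 exclude it. Folds of weakly and very strongly expressed genes are compressed by an unknown amount, so a gain need not read as 0.58. These counts therefore cannot decide, and a gain of the whole run stays open. A gain of part of the run or an effect of an inserted transgene on its neighbours may also account for the higher run. So may a stretch of chromosome from another founder strain. Probes mismatched on the arrays labelled MLC-SOCS-3 would lower signals. With the labels as given, such probes stay open for the lower Ikbip, Slc25a3 and Nedd1 beside the run, but not for the higher run. Apart from the interval counts, none of these was tested, and array values give no genomic copy number.

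Socs3 was not higher on the arrays labelled MLC-SOCS-3, where a transgene read by the probes would raise it. The chromosome 10 scan separated the arrays as labelled, and every other split stayed at or below 5.16. That speaks against an exchange of labels between 1 array of each group only if the run goes with the transgene, which was not tested. The 6 Socs3 values spanned 0.36 on the log2 scale, and probes outside the transgene's sequence may explain this. An exchange of the names of the whole groups would turn the Socs3 difference of -0.26 (adjusted p = 0.80 in limma) into a rise of that size. So small a rise argues against such an exchange as the only reason that no strong Socs3 signal was seen. Whether the names were exchanged stays open, since the table has 1 value per probe set and no separate measure of the transgene. Lower Cish and Socs2 could reflect a weaker response to cytokines in muscle with more SOCS-3, a hypothesis. The median of the 10 other induced targets was -0.079, at percentile 1.83 of 10000 random lists matched on level. Those random lists do not keep the correlation between genes that vary together, so the percentile can overstate how unusual the median is. Of the 10 targets, 4 were positive, and Junb, Fos and Myc also belong to the immediate-early list, so this does not decide. Socs2 itself lies on chromosome 10, and its other probe set gave only -0.38.

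The connective tissue list had the smallest p of the lists in camera with the preset correlation. Its lowest array mean, -0.16, was however on MLC-SOCS-3 replicate 1, below all 3 controls. Differences between single muscles may therefore account for the call as well as the transgene, and the estimated correlation of the list's genes was 0.43. A group effect on part of the arrays was not tested and stays open.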
